A study of Mus musculus with 5 samples.

How the data were processed

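The series measured gene expression in ovarian granulosa cells of mice with Affymetrix 3' expression arrays of 45101 probe sets. There were 5 arrays, 1 for each of 5 groups. Per the labels, the mice were given equine chorionic gonadotropin (eCG), which drives follicle growth, for 48 h and then human chorionic gonadotropin (hCG), which stands in for the ovulatory surge of luteinizing hormone. Cells of the double knockout were collected 4, 8 and 24 h after hCG, and cells of wild type 8 and 24 h after hCG. A wild type at 4 h was not analysed here. The knockout carried floxed alleles of the genes for C/EBPα and C/EBPβ and a Cyp19-cre transgene, which expresses the recombinase in granulosa cells. Per the labels, the animals were 23 days old at 4 and 8 h and 24 days old at 24 h. The group of each array was taken from its title.

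Per the labels' protocols, total RNA was extracted with RNeasy kits and biotin-labelled cRNA was made from 5 ug of it. The authors' deposited values are intensities, and the submitters' processing notes name affy and RMA, with no version. RMA usually returns log2 values, but the deposited table holds whole-number intensities on a linear scale, so log2 was taken before every comparison. Rounding to whole numbers makes log2 differences coarse at low intensity. The quantiles of 4 of the arrays nearly coincided, with a mean range of 0.05 on the log2 scale between sorted values above the floor. The knockout array at 4 h was not on that scale. Its median intensity was 54, against 31 or 32 on the other arrays. Whether it was normalized together with the others is not given in the sources used here.

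Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers from a RefSeq gene table of GRCm38.p6, used for names only. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none listed, and 34754 of the identifiers matched the gene table. Only probe sets with 1 symbol were used. A gene was represented by its probe set with the highest mean over the 5 arrays, which gave 18194 genes. No coordinates are given, because no genome build is stated in the sources used here.

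With 1 array per group there are no replicates, so single comparisons have no test and no p-value. A size rule took their place. A gene passed when its intensities differed by at least 2-fold, a log2 difference of 1, and the higher of both values reached a floor set at the 40th percentile of all values, an intensity of 22. Where the lower value lay under the floor, the fold was computed against the floor and is given as "at least". Log2 differences and list medians otherwise use values as measured. They were computed again with values under the floor raised to it after the data had been examined, and those values are given where they matter. For the difference of the 8 h to 24 h changes, the highest of the 4 values had to reach the floor. The number of arrays limits the precision. The agreement of different probe sets of a gene measures the technical spread only. It was 0.26 on the log2 scale (SD per probe set) for the genotype difference at 8 h and 0.36 at 24 h. For genes past the rule, a second probe set above the floor went the same way in 93.1% at 8 h and 91.6% at 24 h. It also passed the rule in only 65.2% at 8 h and 44.1% at 24 h. The 18 hybridization control probe sets varied with an SD of 0.09 at 8 h and 0.04 at 24 h.

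The genotype effect averaged over 8 h and 24 h was fitted with limma 3.58.1 in R 4.3.3 on 4 arrays, with genotype and time as terms, eBayes with a trend and Benjamini-Hochberg adjustment at 0.05. Its 1 residual degree of freedom is the interaction of genotype and time, not replicate error. The knockout array at 4 h was left out for want of a wild-type partner. On simulated data for 13316 genes with 200 changed, this fit recovered 93% of the changes of log2 size 1 and 100% of those of size 2, with 2 false calls among 195. The simulated noise was even across genes, with an SD of 0.20 and no interaction. In the real fit the interaction is the only residual, so these rates do not carry over to it. With the same simulated noise and no difference, 1 of 13316 genes passed the size rule between a pair of arrays. That noise was set from the genotype difference at 8 h, with a robust SD (from the median absolute deviation) of 0.28 over genes. At 24 h that SD was 0.42, so the count does not carry over to 24 h. Nor does an even noise describe values near the floor.

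The 15 gene lists and 7 lists of cell type markers were fixed before the data were examined, as were the comparisons, the size rule and the rule for named genes. For each list, the median log2 difference of members above the floor was set beside 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays and is no p-value. On simulated data for 13052 genes, 5.0% of 60 unchanged lists of 20 genes fell outside the 2.5th to 97.5th percentile, and a shift of 0.5 on the log2 scale was found in 100% of them. The simulated genes varied independently, whereas members of a real list may vary together, so these rates do not carry over to the real lists. Several lists share members. Some members, among them genes central to granulosa biology, had no probe set of 1 symbol here and are not reported.

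The named genes were Cebpa and Cebpb, the 10 largest differences each way in each genotype comparison, and the 5 largest each way in each time change and in the difference of changes, leaving out clone-like and predicted symbols. From each list, up to 4 members past the size rule each way were named, or otherwise the 2 members of largest difference. Further members named beyond this rule are said to be so.

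Alternatives were the mean over all probe sets of a gene, leaving out probe sets whose identifiers end in _x_at or _s_at, no floor, a floor at the 60th percentile, quantile normalization, median centring, cyclic loess, thresholds of 1.5-fold and 3-fold, and for limma other variance moderation and an adjusted p of 0.01. One more was added after the data had been examined, namely choosing probe sets and the floor without the knockout array at 4 h. To examine a bias of intensity, list members were compared with the median of other genes in the same of 20 bins of mean expression, a test chosen after the data had been examined. Intervals for medians are 95% bootstrap intervals over genes from 10000 draws, and genes are not independent replicates. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used.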

Results

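Granulosa cells of wild-type mice and of mice with a granulosa cell knockout of C/EBPα and C/EBPβ, per the labels, were profiled after an ovulatory dose of hCG, 1 array per group and no replicates. C/EBPα and C/EBPβ are transcription factors of the basic leucine zipper class, and the series asked which genes need them during ovulation and luteinization. Across 15327 genes, log2 intensities of the wild-type and knockout arrays correlated with r = 0.98 at 8 h and r = 0.97 at 24 h. The knockout array at 4 h correlated with the others at r = 0.86 to 0.91. Genes are not independent replicates, and every difference below is between single arrays.

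Both targeted genes were lower in the knockout arrays than in wild type. Cebpa (probe set 1418982_at) had an intensity of 685 in wild type at 8 h and 19 in the knockout, at least 31.1-fold lower. At 24 h it was 352 against 38, 9.26-fold lower. Cebpb (1418901_at) was 7436 against 1127 at 8 h, 6.60-fold lower, and 3976 against 85 at 24 h, 46.8-fold lower. Its second probe set (1427844_a_at) gave 2926 against 275 at 8 h and 1571 against 23 at 24 h. In the knockout at 4 h, Cebpa was 40 and Cebpb 42 and 25 on its 2 probe sets. The knockout had more Cebpb signal at 8 h than at the other times, above the 75th percentile of that array, which was 177. The labels do not say which part of each gene is deleted, so how far these probe sets check the deletion is unknown.

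**Figure D1:**
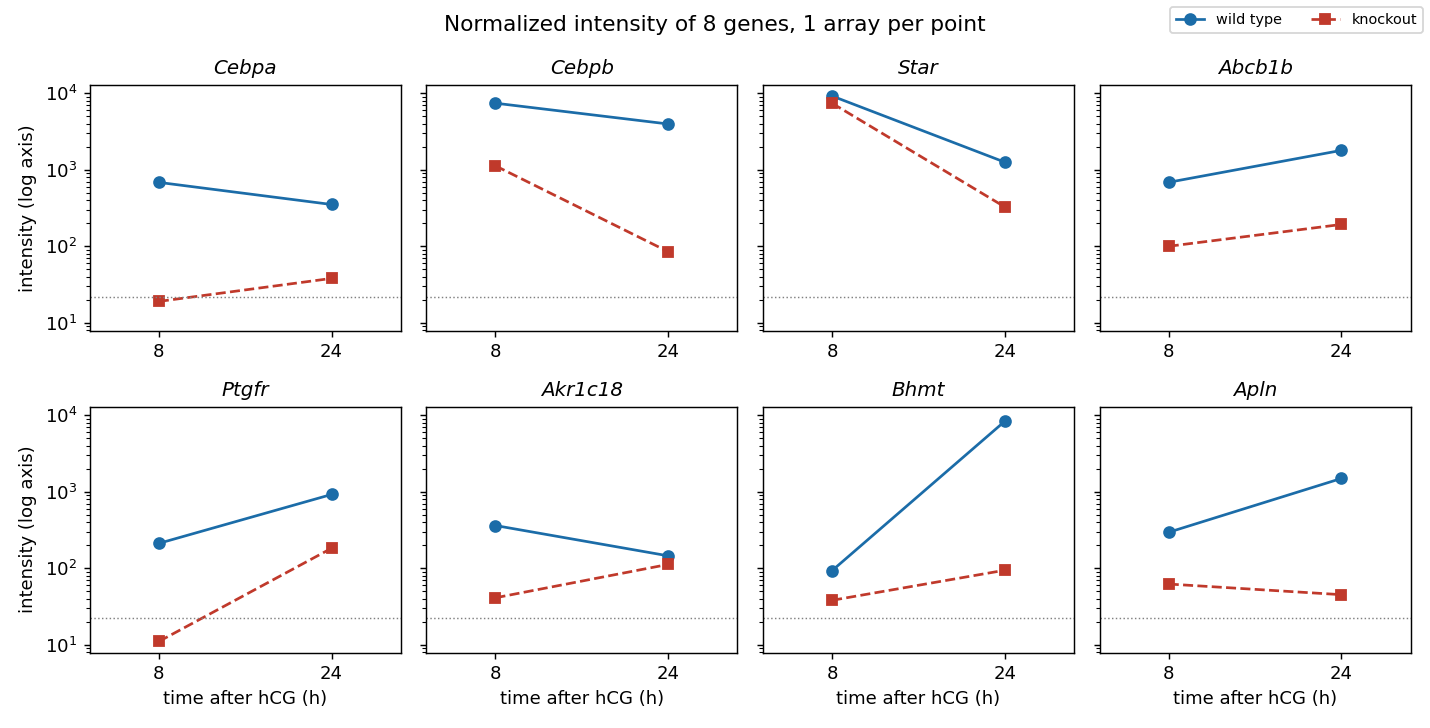
Intensity on a log axis at 8 h and 24 h after hCG for 8 genes, with wild type as circles and the knockout as squares, 1 array per point, and the floor of 22 as a dotted line. Bhmt reached 8343 in wild type at 24 h and 94 in the knockout, while Akr1c18 differed at 8 h (361 against 41) and lay at 145 against 112 at 24 h.

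At 8 h after hCG, the knockout had lower intensity for most markers of endothelium and stroma and for some luteal markers, and fewer genes were higher than lower. Ptgfr, the prostaglandin F receptor, was 211 in wild type and 11 in the knockout, at least 9.59-fold lower. Akr1c18, an enzyme that inactivates progesterone, was 8.80-fold lower, and Abcb1b, a multidrug export pump, 6.87-fold lower. Edn2, an endothelin peptide, was 5.74-fold higher, and Kl, which encodes Klotho, 5.12-fold higher. In all, 523 genes were lower and 204 higher in the knockout, of 12924 above the floor. The question here was which genes depend on the C/EBP factors at about the time of ovulation. Markers of stroma and endothelium were lower on the same arrays. Neither these counts nor the single genes named for 8 h therefore separate such dependence from a difference in the cells collected.

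Apart from Cebpa and Ptgfr, the largest falls below wild type were in Cldn1, a tight junction claudin (at least 15.1-fold), Rgs5, a pericyte gene (11.3-fold), Ms4a4d (11.1-fold), and Emcn, an endothelial sialomucin (10.3-fold). Rbp4, the retinol carrier, was 9.27-fold lower, Tcf21, a mesenchymal transcription factor, 8.88-fold lower, the matrix proteoglycan gene Fmod at least 7.05-fold lower, and Tnfsf11, which encodes RANKL, at least 3.45-fold lower. On the higher side, Oit3 was 8.19-fold, Trbv1 7.90-fold, Bambi-ps1 7.27-fold, the export pump gene Abcc2 5.78-fold, and Ddc, an aromatic amino acid decarboxylase, 5.47-fold above wild type. Sprr1a was at least 4.59-fold, Creb5 (66 against 7) at least 3-fold and the chemokine gene Cxcl3 at least 1.95-fold higher. Creb5 missed the rule with the mean of its probe sets, and Trbv1 without the less specific probe sets.

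Among the fixed lists at 8 h, luteal markers had a median log2 difference of -0.59, below the 2.5th percentile of matched random lists, with 5 of 19 lower and 1 higher. Bhmt, a methyltransferase of methionine synthesis, was 2.45-fold lower, and Cited4 was 2.76-fold higher, a call lost with the mean of its probe sets. Of 14 steroidogenesis genes, 13 lay below wild type, with a median of -0.37, but Akr1c18 alone passed the rule. Star, which carries cholesterol into mitochondria, differed by -0.31, short of the rule. Ovulatory response genes went both ways, 3 of 24 higher and 4 lower. Edn2 and the EGF-like factor Btc (3.56-fold) were higher, while Ereg, another EGF-like factor (2.30-fold), Ptgs2, the inducible prostaglandin synthase (2.11-fold), the prostaglandin receptor gene Ptger4 (2.12-fold) and Has2, a hyaluronan synthase (at least 1.82-fold), were lower. Their median of 0.11 changed sign to -0.0506 with the mean of all probe sets, under which Ptgs2, Ptger4 and Prkg2 (3466 in the knockout and 1733 in wild type) no longer passed. In prostaglandin synthesis and signalling, 4 of 15 were lower and 2 higher, namely Slco2a1, a prostaglandin transporter (4.98-fold), and Hpgd, which degrades prostaglandins (2.99-fold).

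Immediate early and ERK feedback genes lay above wild type at 8 h, with a median of 0.25 at the 99.99th percentile. Of 23, 4 were higher, namely the phosphatase gene Dusp4 (4.64-fold), Ier3 (3.48-fold), Atf3 (2.71-fold) and Klf4 (2.36-fold), and Dusp1 was lower (2.38-fold). In the cytokine list, Lif (4.06-fold) and Il1r1 (2.97-fold) were higher, the latter not with the mean of its probe sets, and Cxcl12 (5.35-fold) and Saa3 (2.18-fold) lower. Of 25 preovulatory granulosa genes, Grem1, a BMP antagonist, was 3.52-fold higher and Fst, the activin binder, 2.14-fold lower, around a median of 0.16. In the glycolysis and hypoxia list, Hk2, a hexokinase, was 6.09-fold lower, and Bnip3, at 1504 against 3018, was also lower but missed the rule after any of the 3 further scalings. The list's median was nonetheless 0.21. Dhcr7 was the only one of 19 cholesterol biosynthesis genes past the rule (2.57-fold lower). That list had a median of -0.24, at the 0.01th percentile, with 13 of 19 below wild type. Among proteases, Mmp2 and Mmp19 were lower (3.55- and 3.56-fold) and the plasminogen activator gene Plau higher (2.41-fold). None of 28 cell cycle, 14 apoptosis or 12 housekeeping genes passed, with medians of 0.01, -0.04 and -0.02. The members of largest difference were Rrm2 (0.54) and Ttk (-0.28), Apaf1 (0.97) and Bid (-0.93), and Hprt (0.48) and Pgk1 (0.45).

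Markers of other cell types differed between the same arrays at 8 h. Stroma and smooth muscle markers had a median of -2.16 (-1.99 with values under the floor raised to it), with 13 of 15 lower in the knockout, among them the myosin gene Myh11 (6.64-fold), the matrix genes Lum (5.94-fold) and Mgp (5.43-fold), and Ogn (5.23-fold). Endothelial markers had a median of -1.62 (-1.503 with the floor), with 15 of 18 lower, among them Sox18 (3.58-fold), Tek (at least 3.68-fold) and Fli1 (at least 3.14-fold). Theca markers had a median of -0.79, with 3 of 8 lower, namely Tcf21, Fbln5 and the androgen synthesis gene Cyp17a1 (2.77-fold). The angiogenic factors had a median of -0.45, with Edn2 higher and 6 of 21 lower, among them Vegfd (5.67-fold), the apelin gene Apln (4.76-fold), Nrp1 (3.01-fold) and Angpt1 (13 against 55, at least 2.5-fold). The call for Angpt1, like that for Fbln5, was lost with the mean of the gene's probe sets. Of 17 leukocyte markers, 4 were lower, namely Lyz2, Fcgr3, C1qa and C1qc, and Cd52 was higher (2.78-fold), with a median of -0.52. Krt8 (2.35-fold) and Krt18 (2.13-fold) of the surface epithelium list were higher. Oocyte markers had a median of -0.09 and none passed, with Dppa3 at -0.45 and Bmp15 at -0.36. Of 3 erythroid markers above the floor, Alas2 was lower (2.39-fold).

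In the list of C/EBP family genes and regulators, Cebpa and Cebpb were the only ones of 8 above the floor past the rule, with a list median of -0.22 at 8 h and -0.37 at 24 h. At 8 h the medians of the lists of prostaglandin, cytokine and protease genes were -0.27, -0.14 and -0.16, and those of surface epithelium and erythroid markers 0.13 and -0.20.

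At 24 h, when granulosa cells luteinize, the knockout had lower intensity for cholesterol biosynthesis, glycolysis and luteal genes. Bhmt was 88.8-fold lower, at 94 against 8343. Sc5d, Mvd, Dhcr7 and Fdps of the cholesterol pathway were 3.59- to 5.05-fold lower, and all 19 genes of that list lay below wild type. Apln was 33.1-fold lower, and Star, 1259 in wild type, was 3.85-fold lower. In all, 511 genes were lower and 408 higher, of 13052 above the floor. With the mean of all probe sets 417 were lower and 249 higher, and at a 1.5-fold threshold the balance turned, to 1347 lower and 1508 higher.

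Other large falls below wild type at 24 h were in Hp, which encodes haptoglobin (21.5-fold), the chemokine receptor gene Cxcr4 (20.5-fold), the peptidase gene Mmel1 (30 against 601), Slc12a8 (19.8-fold), Parvb, an integrin-linked parvin (65 against 1169), Ppp1r14a, an inhibitor of myosin phosphatase (15.2-fold), and the lipid kinase gene Pik3c2g (at least 10.5-fold). The largest differences above wild type were in Car12, a carbonic anhydrase (18.8-fold), the Ras exchange factor gene Rasgrf2 (17.7-fold), Sprr1a (at least 12.5-fold), Lrmp (7.68-fold), the semaphorin gene Sema3e (7.09-fold), Tnnt1 (448 against 64), Scara3 (6.71-fold) and Tnxb, a tenascin (6.67-fold). Gfi1, a transcriptional repressor, was at least 5.27-fold and Npr3, the natriuretic peptide clearance receptor, at least 5.23-fold higher.

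The cholesterol biosynthesis list had a median of -1.32 at 24 h, with 13 of 19 past the rule. Beyond the named rule, Sqle (-1.44), Nsdhl (-1.59) and Msmo1 (-1.61) were among them. Fdps missed the rule with the mean of its probe sets (-0.92). The glycolysis and hypoxia list had a median of -0.50, with 7 of 19 lower and none higher. Hk2 was 5.45-fold, the lactate dehydrogenase gene Ldha 3.05-fold, Egln3 2.65-fold and Pfkp 2.49-fold lower, the last 2 not with the mean of their probe sets. Luteal markers had a median of -0.61 with 5 of 19 lower, namely Bhmt, Abcb1b (9.31-fold), Parm1 (5.05-fold), Ptgfr (5.05-fold) and Hsd17b7, and Cdkn1a, a cell cycle inhibitor, was higher (2.30-fold). Of 14 steroidogenesis genes, Star and Hsd17b7 (3.01-fold) were lower, with a median of -0.35. Of 21 ovulatory response genes above the floor, 4 were lower and none higher, namely Ereg (3.12-fold), Pcsk5 (2.83-fold), Edn2 (2.51-fold) and Ptgs2 (at least 2.14-fold, lost with the mean of its probe sets). Their median was -0.20.

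Preovulatory granulosa genes lay above wild type at 24 h, with a median of 0.38 at the 99.99th percentile. Grem1 (3.74-fold), Mro (2.81-fold), Kitl, the kit ligand (2.45-fold), and Kctd14 (2.24-fold) were higher and none of 25 lower. Kitl was at 0.31 with the mean of its probe sets. Of 23 immediate early and ERK feedback genes, 5 were higher and 3 lower. Dusp4 (5.39-fold), Ier3 (4.19-fold), Egr3 (at least 2.73-fold) and Egr2 (at least 2.09-fold) were higher, with both Egr genes short of the rule by the mean of their probe sets, and Dusp1 (7.39-fold), Myc (2.78-fold) and Fosl1 (at least 1.95-fold) lower. Angiogenic factors had 6 of 21 lower, with Nrp1 at 6.44-fold and Angpt1 at least 4.41-fold, and 2 higher, Vegfc (2.32-fold) and Pdgfa (2.20-fold). Of the cytokine list, Saa3 (5.37-fold) and Ccl2 (2.10-fold) were lower with Cxcr4. Il1r1 was higher (2.63-fold), and not with the mean of its probe sets. Proteases and their inhibitors went both ways, with Mmp11 (3.98-fold), Timp2 (2.60-fold) and Adamts9 (2.28-fold) higher and Pcsk5, Timp3 (2.70-fold), Serpina3n (2.13-fold) and Mmp19 (15 against 33, at least 1.5-fold) lower. In prostaglandin signalling, Slco2a1 was higher (3.05-fold) and Ptgfr and Ptgs2 were lower, of 14. List medians were 0.18 for immediate early, -0.29 for angiogenic, -0.32 for cytokine, -0.04 for protease and 0.14 for prostaglandin genes. Adamts9, Timp2, Slco2a1 and Vegfc were not called with the mean of their probe sets.

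Cell cycle, apoptosis and housekeeping medians at 24 h were 0.17, 0.27 and -0.20. Of these lists, Pgk1 alone passed, 2.19-fold lower and lost with the mean of its probe sets. The largest members otherwise were Bub1b (0.70), Mcm7 (0.62), Bcl2l11 (0.86) and Apaf1 (0.74). Endothelial, stroma, theca and leukocyte medians lay nearer 0 than at 8 h, and oocyte and surface epithelium medians farther from 0. Endothelial markers had a median of -0.63, with Emcn (5.74-fold), Cldn5 (2.92-fold) and Cdh5 (2.26-fold) lower and Ramp2 higher (4.44-fold) of 18. Stroma and smooth muscle markers had a median of -0.42, with Mgp (2.28-fold) and Pdgfrb (2.19-fold) lower of 14. Leukocyte markers had a median of -0.30, with S100a8 (at least 2.95-fold), Lyz2 (2.28-fold) and Ptprc (2.24-fold) lower of 17. Cdh5, Pdgfrb and Ptprc missed the rule with the mean of their probe sets. The theca list had Aldh1a1 higher (3.71-fold) and Star lower, with a median of 0.10. Krt7 was the surface epithelium marker past the rule (2.12-fold lower), with a list median of -0.49. Oocyte markers had a median of 0.47 and none passed, with Omt2a at 0.97 and Omt2b at 0.76. Erythroid markers had a median of 0.07, with Slc4a1 at 0.22 and Hbb-b2 at -0.20.

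**Figure D2:**
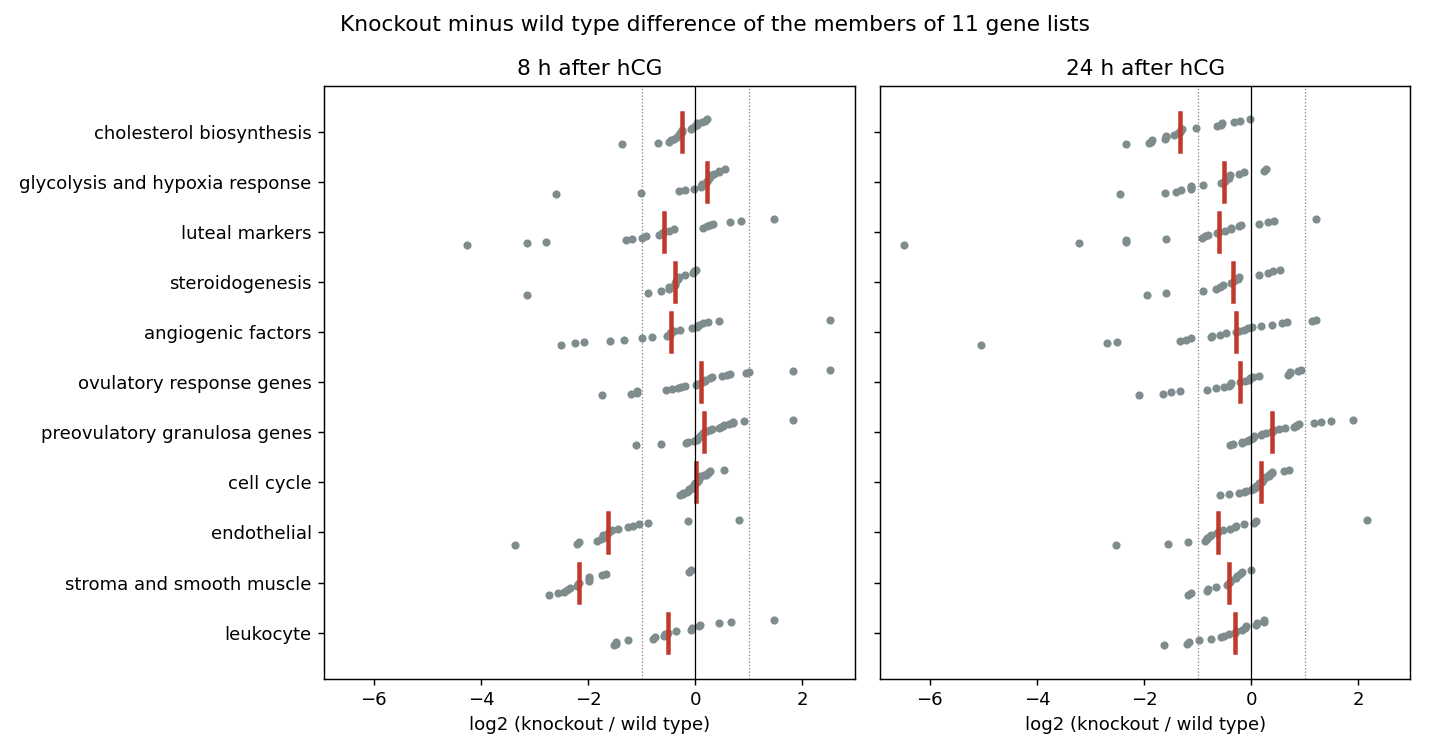
Log2 ratio of knockout to wild type for the members of 11 gene lists at 8 h (left) and 24 h (right), with 1 grey point per gene above the floor, the list median as a red bar and the 2-fold rule as dotted lines. Stroma and endothelial medians lay at -2.16 and -1.62 at 8 h, and the cholesterol biosynthesis median moved from -0.24 at 8 h to -1.32 at 24 h.

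Many of the same genes differed at both times. Of 12660 genes above the floor at both, 137 were lower in the knockout at 8 h and at 24 h, where independent lists would share 18.4, and 60 were higher at both, against 5.40. Abcb1b, Hk2, Ptgfr, Apln, Nrp1 and Emcn were lower at both, and Sprr1a, Kl, Dusp4, Ier3 and Grem1 higher. In opposite directions, 2 genes were higher at 8 h and lower at 24 h, and 6 the reverse. Across genes the differences at the 2 times correlated with r = 0.43. The arrays of the 2 times are separate, so no array is shared between these differences.

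**Figure D3:**
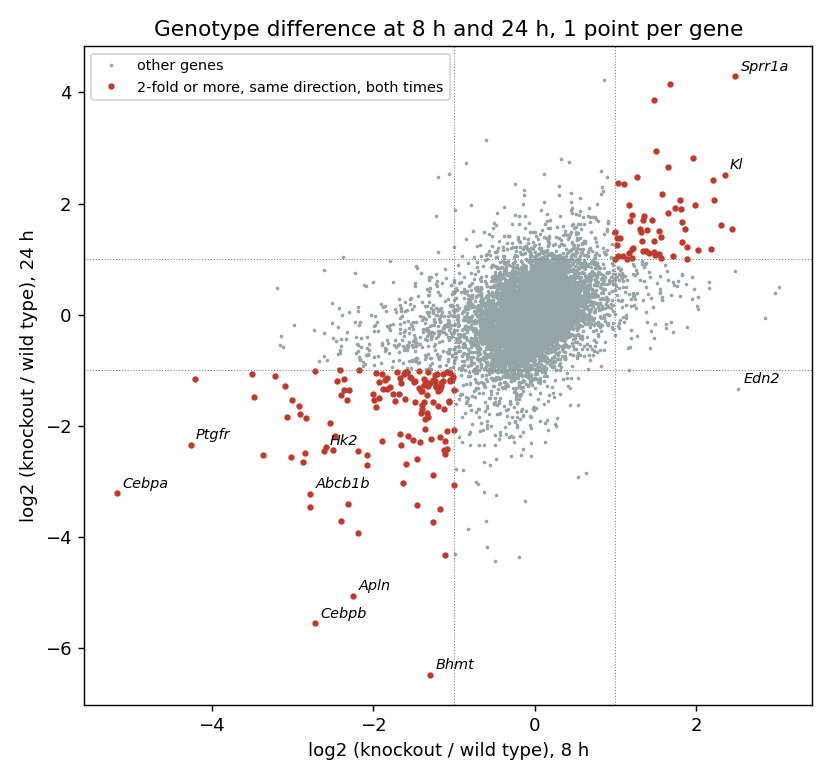
Log2 ratio of knockout to wild type at 8 h (horizontal axis) and 24 h (vertical axis), 1 point per gene above the floor at both times, with dotted lines at the 2-fold rule. Red points are the 197 genes past the rule in the same direction at both times, and Edn2 lies at 2.52 and -1.33.

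From 8 h to 24 h, most ovulatory response genes fell in both genotypes. In wild type, Sult1e1, an estrogen sulfotransferase, fell 226-fold, the neuropeptide gene Nts 144-fold, Gsta2 at least 83.6-fold, Lyve1, a hyaluronan receptor, 67.0-fold and Ptx3, a matrix protein of the cumulus, 55.1-fold. Bhmt rose 89.7-fold, Rab27a 26.7-fold, Timp4 at least 26.1-fold, Slc12a8 22.5-fold and Mmel1 21.5-fold. In the knockout, Sult1e1 fell at least 295-fold, Nts 214-fold, Gsta2 81.0-fold, Gcg at least 42.2-fold and Snap25 at least 36.1-fold, and Oxtr, the oxytocin receptor (31.3-fold), Ccn5 (31.3-fold), Tnxb (at least 27.6-fold), Spns2 (26.5-fold) and Niban1 (21.6-fold) rose. These also rose in wild type, Oxtr 14.3-fold, Ccn5 8.21-fold, Spns2 3.32-fold, Niban1 3.18-fold and Tnxb 2.53-fold, and at 24 h Oxtr was 3.43-fold lower in the knockout than in wild type. There were 724 genes higher and 842 lower at 24 h in wild type, and 890 higher and 684 lower in the knockout. Neither balance held throughout, with 786 higher and 769 lower in wild type after median centring and 249 higher and 288 lower in the knockout at a 3-fold threshold. Genes that rose in both genotypes numbered 338 and genes that fell in both 413, against 46.7 and 41.7 for independent lists, with r = 0.70 across 12737 genes.

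Ovulatory response genes fell in both genotypes, 18 of 24 in wild type and 15 of 23 in the knockout, with medians of -1.96 and -2.53. With values under the floor raised to it, the wild-type median was -1.53. Cell cycle genes had medians of -0.90 and -0.70, with 9 and 7 of 28 lower at 24 h. Of the cholesterol biosynthesis genes, 7 of 19 were lower at 24 h in wild type, with a median of -0.45, and 13 of 19 in the knockout, with a median of -1.68. Star fell in both, with log2 changes of -2.87 in wild type and -4.50 in the knockout. Luteal markers had a median change of 0.79 in wild type and 0.24 in the knockout. Preovulatory granulosa genes had a median change of 0.45 in wild type and 0.59 in the knockout, so that list as a whole fell in neither genotype. Stroma markers had a median of -0.70 in wild type and 0.69 in the knockout. Endothelial markers were at -0.88 and 0.20, theca markers at -1.40 and -0.06, and leukocyte markers at 0.58 and 0.61, in the same order.

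The change from 8 h to 24 h differed between the genotypes by at least 2-fold in 1083 of 13316 genes, more positive in the knockout for 671 and more negative for 412. Bhmt (-5.18), Cxcr4 (-4.16), Mpzl2 (-3.98), Hp (-3.93) and Edn2 (-3.85) had the most negative differences of log2 changes, and Npr3 (3.75), Smpx (3.68), Fmod (3.68), Cntnap5a (3.60) and Tnxb (3.59) the most positive, ranked on values as measured. With values under the floor raised to it, the difference was -3.53 for Mpzl2, 2.99 for Npr3, 3.31 for Fmod, 2.60 for Cntnap5a and 3.45 for Tnxb. Mpzl2 rose at least 11.6-fold in wild type and was under the floor in the knockout at both times. With 1 array per group this difference was not tested. After median centring the split was 511 against 524.

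Within the knockout, Pgr, the progesterone receptor that hCG induces early, was 9080 at 4 h and 71 at 8 h. Depp1, Hey1, Slitrk6 and Tnfsf11 were also lower at 8 h, and S100a6, Anp32a, Cebpb, Lyve1 and Hspb1 higher. The array at 4 h was brighter throughout. The median log2 difference of all genes, 8 h minus 4 h, was -0.78 as deposited and 0.08 after quantile normalization, so the values that follow are after quantile normalization. Pgr differed by -6.20, Depp1 by -5.90 and Hey1 by -5.02. Slitrk6 was at least 20.9-fold and Tnfsf11 at least 11.7-fold lower at 8 h, where both were under the floor. S100a6 differed by 7.69, Anp32a by 6.49, Cebpb by 5.56, Lyve1 by 5.27 and Hspb1 by 5.18. The count was 6062 genes lower and 838 higher at 8 h as deposited, and 1641 lower and 2461 higher after quantile normalization. Gapdh control probe sets had a 3' to 5' ratio of 3.86 at 4 h against 0.97 to 1.05 on the other arrays, and beta-actin 3.87 against 1.36 to 1.496. As deposited, different probe sets of a gene agreed poorly in this comparison, with r = 0.44 and an SD per probe set of 0.79. The hybridization controls varied with an SD of 0.31. Single genes and small list medians here are therefore uncertain. After quantile normalization, cholesterol biosynthesis genes had a median of 0.98, with 8 of 19 higher at 8 h and 2 lower, luteal markers 0.72, with 8 of 20 higher and 3 lower, and preovulatory granulosa genes -0.65, with 6 of 25 lower and 2 higher. Medians were -0.70 for steroidogenesis, -0.69 for oocyte, -0.49 for prostaglandin, -0.47 for cell cycle, 0.51 for housekeeping and 0.78 for endothelial genes, each outside the range of 95% of random lists. Ovulatory response genes (-0.18, with 4 of 24 higher and 8 lower) and immediate early genes (-0.41, with 1 of 23 higher and 7 lower) lay inside that range.

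The genotype effect averaged over 8 h and 24 h had no gene past an adjusted p of 0.05 among 13316 tested with limma, and 1505 genes had an unadjusted p under 0.05. The smallest adjusted p in limma was 0.254. Among genes at that value, Abcb1b had an averaged log2 effect of -2.9996, Hk2 of -2.53, Kl of 2.44 and Ier3 of 1.93, each in the same direction at both times. The fit takes the genotype by time difference as its error, so genes whose effect differed between the times have a large error in it. Even the targeted genes were not called, with Cebpa at -5.17 at 8 h and -3.21 at 24 h, and Cebpb at -2.72 and -5.55. The count of 0 is therefore no sign that the genotype had no effect.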

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

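Except for the test of 1 scale factor, the tests of explanations in this part were chosen after the results were seen. No group has enough arrays for a test of outlying samples, and none of the opposite directions below was tested, since each group is 1 array.

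The genotype difference passed the size rule in opposite directions at 8 h and 24 h for 5 named genes, and the value given is the 24 h difference minus the 8 h difference on the log2 scale. It was -3.85 for Edn2, which was higher at 8 h and lower at 24 h. It was 3.60 for Cntnap5a, 3.68 for Smpx, 2.996 for Spns2 and 2.21 for Vegfc, which were lower at 8 h and higher at 24 h. At 8 h Cntnap5a was 11 in the knockout, under the floor, and with that value raised to the floor its 8 h difference was -0.06, so that its opposite directions rest on background and its difference was 2.60. The change from 8 h to 24 h passed in opposite directions for Smpx, as above, and for Akr1c18 (2.77), Fmod (3.68), Npr3 (3.75), Ogn (2.39) and Ramp2 (2.28), each lower at 24 h in wild type and higher at 24 h in the knockout. Ogn is in the stroma list and was low in the knockout at 8 h (-2.39) with that list. Ramp2, of the endothelial list, was not (-0.13). A difference in the cells collected was not separated from one in expression. With the floor, Npr3 no longer passed in wild type (at least 1.59-fold lower), with a difference of 2.99, while Fmod still did in both, with 3.31. The Vegfc call at 8 h, at 50 against 100, was lost after quantile normalization (-0.94) and median centring (-0.94). It was also lost without the less specific probe sets (-0.87). Its call at 24 h was lost with the mean of all probe sets (0.93).

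Medians of 4 lists lay outside the range of 95% of random lists in opposite directions. Ovulatory response genes were at 0.11 at 8 h and -0.20 at 24 h, a difference of -0.32. The sign at 8 h turned to -0.0506 with the mean of all probe sets, under which the directions were no longer opposite, and the 24 h median was -0.13 with values under the floor raised to it. Glycolysis and hypoxia genes were at 0.21 and -0.50, a difference of -0.71. For the change from 8 h to 24 h, stroma and smooth muscle markers were at -0.70 in wild type and 0.69 in the knockout, a difference of 1.39, and surface epithelium markers at 0.45 and -0.24, a difference of -0.70.

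Control and unnamed probe sets stood outside the comparisons. The middle 18S ribosomal RNA control probe set read 397 in the knockout and 102 in wild type at 8 h, 3.89-fold higher. The other 18S probe sets read 723 against 121 at the 5' end, 5.98-fold higher, and 709 against 139 at the 3' end, 5.10-fold higher. At 24 h the knockout read lower than wild type, with 121 against 193 in the middle, 154 against 343 at the 5' end and 201 against 211 at the 3' end, and the knockout array at 4 h read 648, 654 and 1023. The 8 h arrays are the pair on which stroma and endothelial markers differed. Among probe sets with no listed gene, 143 passed the size rule at 8 h, 75 higher and 68 lower in the knockout, and 289 at 24 h, 199 higher and 90 lower.

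Markers of stroma and endothelium were lower in the knockout at 8 h, in 32 of 33 above the floor (97.0%), 28 of them past the size rule. A bias of scale or intensity between the arrays, which would move genes of like intensity alike, is argued against. Stroma markers differed by -2.17 at the median (95% interval -2.34 to -1.72) from other genes of the same mean expression. The random lists were matched in the same way on the same arrays, so this restates that comparison and is no separate support. A smaller share of every cell type other than granulosa cells is argued against for oocytes only. The oocyte median lay 1.65 (95% interval 1.45 to 2.07) above that of stroma and endothelial markers. Surface epithelium markers had a median of 0.13. Theca markers went with stroma and endothelium, all 8 below wild type with a median of -0.79, so a smaller share of theca cells is not excluded. The leukocyte median, -0.52, lay 1.22 (95% interval 0.94 to 1.91) above that of stroma and endothelial markers. A smaller share of leukocytes is not excluded, since Lyz2 (-1.48), Fcgr3 (-1.47), C1qa (-1.26) and C1qc (-1.52) were lower while Cd52 was higher (192 against 69). A smaller share of stromal and vascular cells in that preparation remains a candidate explanation, with Mgp, for example, at 1004 against 5454. How many of the markers granulosa cells also express was not analysed here. Lower expression of these genes within cells of the knockout also stays open and was not tested, since the study's genotype and the preparation are the same pair of arrays.

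Cholesterol biosynthesis genes were lower in the knockout at 24 h, with a median of -1.32. The tables argue against a bias of scale or intensity as the whole cause, with a median of -1.41 (95% interval -1.64 to -0.73) relative to other genes of the same mean expression, and against the choice of probe set, with -1.10 (-1.56 to -0.84) for the mean of all probe sets. The first of these values restates the comparison with matched random lists and is no separate support. Preovulatory granulosa genes lay 1.704 (1.01 to 2.13) above the cholesterol median. That list itself was higher in the knockout at 24 h, with a median of 0.38, so it is no neutral gauge of granulosa cells. A smaller share of granulosa cells is therefore not excluded. The loss of C/EBP factors may be the source, as a hypothesis that was found on this pair of arrays and not tested. Differences between animals, or between the 2 collections, cannot be excluded without replicates.

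The knockout array at 4 h stood apart from the others. A single scale factor is argued against, since after quantile normalization 4102 genes passed the rule between 8 h and 4 h, 2.61 times the 1572 between 24 h and 8 h. RNA shortened at the 5' end, or short cRNA, is a candidate explanation for part of it. The lower of its Gapdh and beta-actin 3' to 5' ratios, relative to the highest of the other arrays, was 2.59 times. A biological difference of 4 h from 8 h stays open, and which genes owe their change to which was not tested.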

How the results depend on the processing

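Choosing probe sets and the floor without the knockout array at 4 h was added after the data had been examined. Of 81 alternative values of the 8 counts, 64 stayed within 1.5 times, and the limma count was 0 in each setting, with 1382 to 1784 genes at an unadjusted p under 0.05. Beyond that, by construction, thresholds of 1.5-fold and 3-fold gave 1708 and 269 genes for the genotype at 8 h, 2855 and 288 at 24 h, 3633 and 588 for time in wild type, 3639 and 537 in the knockout, 10440 and 2930 for 8 h against 4 h, 2961 and 332 for the difference of changes, and 645 and 46 shared between times. For 8 h against 4 h, 6900 genes (838 higher, 6062 lower at 8 h) became 4102 (2461, 1641) after quantile normalization, 4462 (1742, 2720) after median centring and 4070 (2349, 1721) after cyclic loess, since these scalings remove the overall brightness of the array at 4 h. After median centring the difference of changes had 511 genes higher and 524 lower, against 671 and 412. At 24 h the mean of all probe sets gave 249 genes higher and 417 lower, and 1.5-fold gave 1508 higher and 1347 lower, against 408 and 511. For time in wild type, 724 higher and 842 lower became 786 and 769 after median centring, and in the knockout 890 and 684 became 249 and 288 at 3-fold. Without the array at 4 h, 722 of 727 genes were kept at 8 h and 914 of 919 at 24 h. Of 220 alternative list medians, 218 moved by less than the probe set spread. That spread, 0.26 at 8 h and 0.36 at 24 h, is of single probe sets and exceeds many of the list medians, so the tolerance is wide. The ovulatory median at 8 h reversed, to -0.0506 with the mean of all probe sets, and the cause was not tested. Of 908 values for named genes past the rule, 846 moved by less than that spread, none reversed and 37 no longer passed. No paired analysis was possible because each group has 1 array, and leaving out an array leaves the limma model no residual degrees of freedom. Differences near the floor of 22 are limited by the signal over background.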

Other observations

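The test of the myeloid list below was chosen after the result was seen, and those of the liver list, the fat cell list and the timing of the response were set before. The rules for reading the tests set before were changed later, as given below. The 3 target lists were written after the data had been examined, each with some members already seen. Reading each list also without those members was decided after the first results.

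C/EBPα and C/EBPβ control well-known genes in other cell types, and lists of such targets were compared at 24 h. Of 12 myeloid targets above the floor, 8 were lower in the knockout and none higher, with a median of -1.92, or -1.61 with values under the floor raised to it. Hp (-4.42), Slc11a1 (-3.71), Chil3 (10 against 107), Camp (-2.65), Saa3 (-2.42) and Lcn2 (15 against 69) were among the lower ones. The 7 members not recorded as seen beforehand all lay below wild type, 3 past the rule. Their median was -0.98, at a percentile of 0 among random lists. They include Csf1r, Lyz2, S100a8 and S100a9 of the fixed leukocyte list, whose values had been examined. S100a8 (-1.63) and Lyz2 (-1.19) are among the 3 past the rule, so this reading is no independent support. As a hypothesis, granulosa cells may use C/EBP factors at these genes too. Of the 12, 4 are also in the leukocyte list, whose median was -0.30, and a difference in leukocytes was not separated from one in granulosa cells.

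Of liver targets, only 5 were above the floor, with a median of -0.56 at the 1.04th percentile, or -0.35 with values under the floor raised to it. Without Hp, which had been seen, 4 were left, with a median of -0.31 at the 7.19th percentile, so the hypothesis that liver targets are lower cannot be decided. Fat cell targets had a median of -0.16 over 11 members, at the 8.60th percentile, with 7 below wild type and 4 above. The rule set before counted a percentile above 2.5 against the hypothesis. As the 95% interval was -0.64 to 0.31, no decision was drawn here either. Among them Agpat2 was at 298 against 1195, Fabp4 at -1.63 and Cd36 at 1.46.

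The hypothesis that the knockout merely responds later was examined on genes chosen by the mean change of both genotypes. The test set before took a delay to make both rising and falling genes change less in the knockout. It counted either median on the other side of 0 against a delay. This prediction holds only for a delay that lasts to 24 h, since one made up by then would make both change more. The 284 genes that fell had a knockout minus wild-type change of -0.20 at the median (95% interval -0.35 to -0.05), a slightly larger fall in the knockout. By the rule set before, this median counts against a delay that lasts to 24 h. The 218 genes that rose had a median of -0.00 (-0.15 to 0.18). Both sets of genes had a mean change of at least 1.5 on the log2 scale, a threshold the hypothesis did not fix. The rule was later widened to allow a delay made up by 24 h, and under it the values leave a delay undecided. At 1 the medians were 0.06 for 627 rising and -0.00 for 647 falling genes, and at 2 they were 0.37 for 91 and -0.35 for 141.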
